A study of Mus musculus with 16 samples.

How the data were processed

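Airway epithelium of wt and Itgb6 ko mice was hybridized to one-colour 4x44K mouse arrays, with 0.5 ug of RNA labelled with Cy3, per the labels' protocols. Mice were 6 to 8 weeks old at sensitization, per the labels. The scanner files hold processed signals in intensity units after background subtraction, as deposited, together with the median intensity of each spot and flags per spot, per the file headers. Feature Extraction was version 10.5.1.1 per the file headers and 10.1 per the submitters' processing notes. The deposited series table holds log2 values. Within each array they ranked the probes as the median spot intensity does (Spearman's rho at least 0.99999), and their medians lay between 5.90 and 5.94. The files hold no mean spot signal, so the median took its place where an alternative named the mean.

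Control spots and spots flagged as non-uniform or population outliers were left out, and repeated spots of 1 probe were averaged. Signals were divided by the 75th percentile of the array, set to no less than a common floor of -3.32 on the log2 scale, and log2 transformed. The floor is the highest among arrays of the lowest signal called well above background. Of 41174 probes, 25615 were well above background on at least 4 of 16 arrays and were kept. The brightest probe stood for each gene, which left 18566 genes and unnamed transcripts that left the floor on at least 1 array, 12850 of them with a symbol. Symbols came from RefSeq accessions, which matched 24844 probes. That annotation is of GRCm38.p6, whereas the arrays were designed on mm9, so no coordinates are printed and distances to Itgb6 come from the annotation alone. Of 564 listed genes 454 were measured, and Tpsab1 had no matched probe. A fold against a group with no array above background, or with all arrays at the floor, is a lower bound. Of the called genes with several probes, 6 of 123 for OVA in wt and 1 of 32 for OVA in ko had a probe of the opposite sign.

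All 16 arrays were fitted together in limma 3.58.1 under R 4.3.3, with 1 mean per group, moderated variances and Benjamini-Hochberg adjustment over all genes at 0.05. The contrasts were OVA against saline in each genotype, ko against wt after each agent, and the interaction. Gene lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated, and with fry, adjusted over all lists and contrasts. The calls that held with an estimated correlation were the mucous cell list with OVA in both genotypes, the endoplasmic reticulum stress and alveolar lists with OVA in ko, and the mast cell list in both comparisons of ko with wt and in the interaction. The other calls made with the preset correlation did not hold with an estimated correlation. Fry passed the calls that held and some of the others. Its adjusted p with OVA in wt was 0.000371 for the mast cell list and 0.000264 for endoplasmic reticulum stress. It was 0.00768 for the type 2 response and 0.00946 for club cells in wt, and 0.0102 for the type 2 response with OVA in ko. Groups, contrasts, filters, lists and most alternatives were chosen before the data were examined. Named genes were fixed by a rule of that time: Itgb6 and the mast cell proteases in every contrast, the 10 genes with a symbol and the largest change in each direction, and up to 4 called members per list, or the 2 with the smallest p where none was called.

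The remaining lists gave these medians with OVA in wt and in ko. Values were -0.13 and 0.85 for the basophil list, of which 2 genes were measured and no test was made, -0.51 and 0.59 for eosinophils, and -0.09 and 0.16 for alarmins and epithelial chemokines. The eosinophil and basophil values in ko rest on ko_OVA 4, and within the slides that hold both groups, which leave that array out, the eosinophil medians in ko were 0.00 to 0.07. Means of the eosinophil list on the other ko_OVA arrays were -3.32 to -3.20, at or near the floor, so these medians do not show the absence of a change. Medians were 0.32 and 0.03 for T cells, 0.46 and -0.19 for B and plasma cells, 0.16 and -0.09 for macrophages and dendritic cells, 0.46 and 0.00 for antigen presentation by MHC class II, and 0.21 and 0.27 for neutrophils. Epithelial lists had -0.46 and 0.13 for basal cells, -0.32 and 0.03 for squamous and oesophageal epithelium, and -0.25 and -0.23 for tuft and neuroendocrine cells. Stromal lists had -0.41 and -0.51 for fibroblasts and smooth muscle, 0.22 and -0.38 for endothelium, 0.27 and 0.21 for cartilage, and 1.53 and -0.25 for adipocytes. Thyroid had 0.01 and -0.24, striated muscle -0.45 and -3.31, and red blood cells 1.14 and 1.11. Pathway lists had 0.01 and 0.00 for TGF-beta targets, 0.02 and -0.01 for the interferon response, -0.30 and -0.05 for the cell cycle, 0.09 and -0.04 for ion transport, and -0.11 and 0.34 for antimicrobial and acute phase genes. The last lists had -0.23 and 0.17 for immediate early and heat shock genes, 0.04 and -0.04 for integrins, -0.07 and -0.10 for neighbours of Itgb6, and -0.29 and -0.64 for sex-linked genes. None of the lists in this paragraph that were tested passed with an estimated correlation in any contrast.

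The method was tested on 10 sets of simulated data for OVA in wt, each with 200 of 18566 genes changed. Changed genes were drawn from those with a wt_saline mean more than 1 above the floor on the log2 scale, so dimmer genes were not covered. The model called 75.5% of genes changed by 1 on the log2 scale, 93.1% of those changed by 2 and 97.3% of those changed by 3. On average 5.92% of the calls were false, with 1.71% to 10.7% in single sets, so a single list of calls can hold more than the nominal 5%. In the simulated comparison of ko with wt after saline, where no gene was changed, 0 of the 10 sets gave a call. A list shifted by 1 in the simulated comparison of OVA in ko was called in all 10 sets. Simulated genes varied independently, whereas that list, of ciliated cells, had an estimated correlation of 0.418 in the real data. The simulation therefore does not show how often a list of correlated genes is called.

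Slide, array position and scan day come from the file headers. Each slide held mixed groups, and each contrast had 3 slides with both of its groups. Array position was less balanced: position 2 held only wt arrays, position 3 only ko arrays and position 4 only OVA arrays. Position is therefore partly aligned with genotype and with OVA. A call lost with position as a fixed block does not show that position caused it. The alternatives covered background correction, normalization, filters on dim probes, outlier spots, probes of a gene, the variance model, array weights, the samples in the fit, slide, scan day, position, a replicate block and the deposited series table. Others were chosen after seeing the data: a lower and a higher floor, a further filter, the level of Y-linked transcripts or of striated muscle genes as a covariate, and leaving out ko_OVA 4 with wt_OVA 1. No sample was left out of the comparisons reported.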

Results

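RNA of airway epithelium was measured on 16 one-colour expression arrays from mice of the FVB strain. The mice were wild type (wt) or carried a knockout (ko) of Itgb6, the gene of the integrin subunit beta6, which pairs with alpha v on epithelial cells and activates latent TGF-beta. Mice of each genotype received saline or ovalbumin (OVA), a chicken egg protein used to provoke allergic airway inflammation, which gave 4 groups of 4 arrays. Sensitization used 20 ug of OVA on days 1, 4 and 7, and challenge used 10 ug into the nose once a week for 9 weeks, with tissue taken 24 h after the last dose. The 75th percentile of the signal ran from 78.0 intensity units on ko_OVA 4 to 793 on ko_saline 3. The share of probes well above background ran from 43.3% on ko_OVA 4 to 74.5% on wt_OVA 1. The number of arrays limits the precision, and the limma p-values below measure the spread between samples. Those of gene lists with an estimated correlation compare the genes of a list with all others. Fisher's exact test counts genes as its units, so its p-values do not show replication across mice.

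Itgb6, the targeted gene, gave signal on every array. Its brightest probe had a mean log2 signal relative to the 75th percentile of -0.75 ± 0.25 (SD, n = 4) in wt_saline, -0.59 ± 0.04 in wt_OVA, -0.86 ± 0.13 in ko_saline and -1.17 ± 0.36 in ko_OVA. Single arrays ran from -0.93 to -0.39 in wt and from -1.71 to -0.73 in ko, so the genotypes overlapped. Across genotypes the mean was lower in ko by -0.34 on this probe (exact permutation p = 0.00591, two-sided, 8 against 8 arrays) and by -0.55 on another probe (exact permutation p = 0.0014). A further Itgb6 probe lay at the floor on all 16 arrays. The files do not say whether these probes lie in the disrupted part of the gene, so Itgb6 checks the genotype labels of single arrays in neither direction.

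The comparison of OVA with saline in wt asked how the epithelium of a normal mouse responds to repeated allergen. Genes of mucous cells, which fill the airway with gel-forming mucin, rose strongly: Clca1, a secreted product of goblet cells, rose by 5.34 ± 0.81 on the log2 scale (SE, n = 3 and 4, adjusted p = 0.00488), and Muc5ac, the mucin itself, by 3.47 ± 0.53 (adjusted p = 0.00331). Slc26a4, an anion exchanger, rose by 5.39 ± 0.60 (adjusted p = 0.000322), Scin, which severs actin, by 4.75 ± 0.45 (adjusted p = 0.000109), and Itln1, a lectin, by 3.33 ± 0.35 (adjusted p = 0.000508). Proteases of mast cells rose as well: Mcpt1 by at least 4.53 (adjusted p = 0.000232), Mcpt4 by 3.53 ± 0.42 (adjusted p = 0.000625) and Mcpt2 by 2.53 ± 0.20 (adjusted p = 5.11e-05). Mcpt1 and Mcpt2 are made by mast cells of mucosal surfaces. Mcpt1 was at the floor on all 4 wt_saline arrays, which makes its change a lower bound, and reached a mean of 1.21 ± 1.30 (SD, n = 4) in wt_OVA. Mcpt2 was at the floor on 3 of 4 wt_saline arrays, so the size of its change and its error depend on the floor.

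Other named genes that rose with OVA in wt included Adra2a, an adrenergic receptor (3.14), Spink1, a protease inhibitor (3.10), the mast cell genes Cpa3 (2.25), Tpsb2 (2.27) and Il1rl1 (2.27), and Capn9, a protease of mucous cells, which was not above background on any wt_saline array and was at least 8.51-fold higher. Chil4, a chitinase-like protein of the type 2 response, rose by 2.77 ± 0.64 (adjusted p = 0.0389), a call lost without any one of wt_saline 1, 2, 3 and 4, wt_OVA 1, 3 and 4, and ko_saline 1 and 2. Falling genes included Scgb1c1, a secretoglobin (adjusted p = 0.00407), Sftpb, a surfactant protein (-2.88, adjusted p = 0.000232), Adcyap1r1, a neuropeptide receptor (-2.65), Clec4n, a lectin of myeloid cells (-2.54), Krtap17-1, a keratin-associated protein (-2.29), Akr1c18, a steroid dehydrogenase (-2.09), Aass, an enzyme of lysine breakdown (-2.07), and Gstt1, a glutathione transferase (-1.83). Marco, a scavenger receptor of macrophages, fell as well (adjusted p = 0.0141), and its call was lost without wt_saline 2 or without wt_OVA 3.

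Among the gene lists, 12 of 20 mucous cell genes rose with OVA in wt and 8 did not pass, with 18 rising when adjusted over the list alone. Their median was 1.54 (adjusted p = 0.0226 with an estimated correlation). The median of the mast cell list was 0.97, with 8 of 17 genes rising, 0 falling and 10 rising when adjusted over the list alone, and the shift did not hold with an estimated correlation (adjusted p = 0.0765 with an estimated correlation). Of 21 genes of endoplasmic reticulum stress 9 rose, led by the chaperone cofactors Sdf2l1 (1.44) and Pdia4 (1.26), with a median of 0.78 (adjusted p = 0.0551 with an estimated correlation). The club cell list, for the secretory cells of small airways, had a median of -0.56, with 8 of 19 genes falling, among them Hp (-1.34) and Aox3 (-1.01), and an adjusted p = 0.222 with an estimated correlation. The type 2 response list had a median of 0.54 and 5 of 21 genes rising (adjusted p = 0.253 with an estimated correlation). Ciliated cell genes had a median of 0.35 with 3 of 19 rising, Dnah9 (0.75), Ccdc39 (0.70) and Cfap52 (0.78), and an adjusted p = 0.415 with an estimated correlation. All 3 of these calls were lost with median scaling and with array position as a fixed block. Under median scaling the log2 changes were 0.47 for Dnah9, 0.43 for Ccdc39 and 0.50 for Cfap52. The call of Cfap52 was also lost without wt_saline 1, wt_saline 2, wt_OVA 2 or wt_OVA 3.

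Over all 18566 genes and unnamed transcripts tested in limma with Benjamini-Hochberg adjustment, 289 rose and 196 fell with OVA in wt, of which 116 and 56 changed at least 2-fold. All 43 named genes called in this comparison kept their sign on each of the 3 slides that hold both groups, apart from spots left out on single arrays, and there the mucous list had medians of 1.41 to 1.44 and the mast cell list of 0.68 to 1.16. The balance of the calls depended on the scaling, with 39 higher and 61 lower under median scaling, which moved the median of all genes to -0.246 and lost 19 of the 43 named calls. With array position as a fixed block 72 were higher and 22 lower, and 21 of the 43 named calls were lost, among them Clca1 (log2 change 4.48, adjusted p = 0.0639), Muc5ac (2.98, adjusted p = 0.0645) and Itln1 (2.52, adjusted p = 0.0645). The count also depended on single arrays: it was 236 without wt_saline 1, 236 without wt_saline 2 and 270 without wt_OVA 3.

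The same comparison in ko asked whether the response to OVA needs the integrin. Chil4 rose by 5.80 ± 0.69 (SE, n = 3 and 4, adjusted p = 0.0013), Clca1 by 5.41 ± 0.81 (adjusted p = 0.00884), Itln1 by 3.90 ± 0.35 (adjusted p = 0.000632), Scin by 3.80 ± 0.45 (adjusted p = 0.000932), Slc26a4 by 3.63 ± 0.60 (adjusted p = 0.00971) and Muc5ac by 3.32 ± 0.53 (adjusted p = 0.00862). Ang6, a ribonuclease, rose by 2.49 and Adra2a by 2.25. Scgb1c1 (-2.96), Sftpb (-2.56), Adcyap1r1, Krtap17-1 (-2.30) and Rab6b, a transport GTPase (-2.29), fell. Mast cell proteases did not pass in ko except Mcpt2, which rose by 1.06 ± 0.20 (adjusted p = 0.0255), a call lost without any one of ko_saline 2, ko_saline 3, ko_saline 4, ko_OVA 1, ko_OVA 3 and ko_OVA 4. Mcpt2 was at the floor on 3 of 4 ko_saline arrays, so the size of its rise and its error depend on the floor. Mcpt1 was at the floor on all 4 ko_saline and 2 of 4 ko_OVA arrays and did not pass (at least 0.35, adjusted p = 0.936), and neither did Mcpt4 (0.12 ± 0.42, adjusted p = 1) or Cpa3, the carboxypeptidase of mast cells (-0.11 ± 0.29, adjusted p = 1).

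In ko 10 of 20 mucous cell genes rose with OVA, 17 when adjusted over the list alone, with a median of 1.58 (adjusted p = 0.0114 with an estimated correlation). Of 21 genes of endoplasmic reticulum stress 6 rose, 16 when adjusted over the list alone, with a median of 0.61 (adjusted p = 0.0226 with an estimated correlation). The alveolar epithelium list had a median of -0.39 with 1 of 11 genes falling, Sftpb (adjusted p = 0.0127 with an estimated correlation). Lists of other tissues were lower in the same comparison, striated muscle by a median of -3.31, fibroblasts and smooth muscle of -0.51 and endothelium of -0.38, and these shifts did not hold with an estimated correlation (adjusted p = 0.452, 0.432 and 0.599 with an estimated correlation). The type 2 response list had a median of 0.60 with 4 of 21 rising (adjusted p = 0.236 with an estimated correlation), and the mast cell list had a median of 0.12 (adjusted p = 0.747 with an estimated correlation). In limma 89 genes rose and 50 fell, of which 57 and 29 changed at least 2-fold. With only the 8 arrays of the groups compared 6 rose and 1 fell, and 28 of the 29 named calls were lost, Chil4, Clca1, Scin, Slc26a4 and Muc5ac among them. With striated muscle genes as a covariate 14 of the 29 were lost, among them Clca1 (log2 change 5.21, adjusted p = 0.0596), Slc26a4 (3.64, adjusted p = 0.0525) and Muc5ac (3.04, adjusted p = 0.0597), and under median scaling 15 were. The mucous list had medians of 0.56 to 2.10 within the slides that hold both groups. The count fell to 67 without ko_saline 1, 71 without ko_saline 2, 88 without ko_saline 3, 75 without ko_OVA 2 and 83 without ko_OVA 4.

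Set side by side, the OVA responses of wt and ko shared 76 rising genes and 34 falling genes, where 1.39 and 0.528 would be shared if the calls were independent. The calls are not fully so, since both comparisons use the same variance estimate for each gene. Clca1, Muc5ac, Scin, Slc26a4 and Itln1 rose in both genotypes and Scgb1c1 and Sftpb fell in both. Of the 485 genes called in wt, 471 had the same sign in ko, and 136 of the 139 called in ko had the same sign in wt. Across all tested genes, which are not independent replicates, Pearson's r of the log2 changes was 0.45 and Spearman's rho was 0.424.

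**Figure D1:**
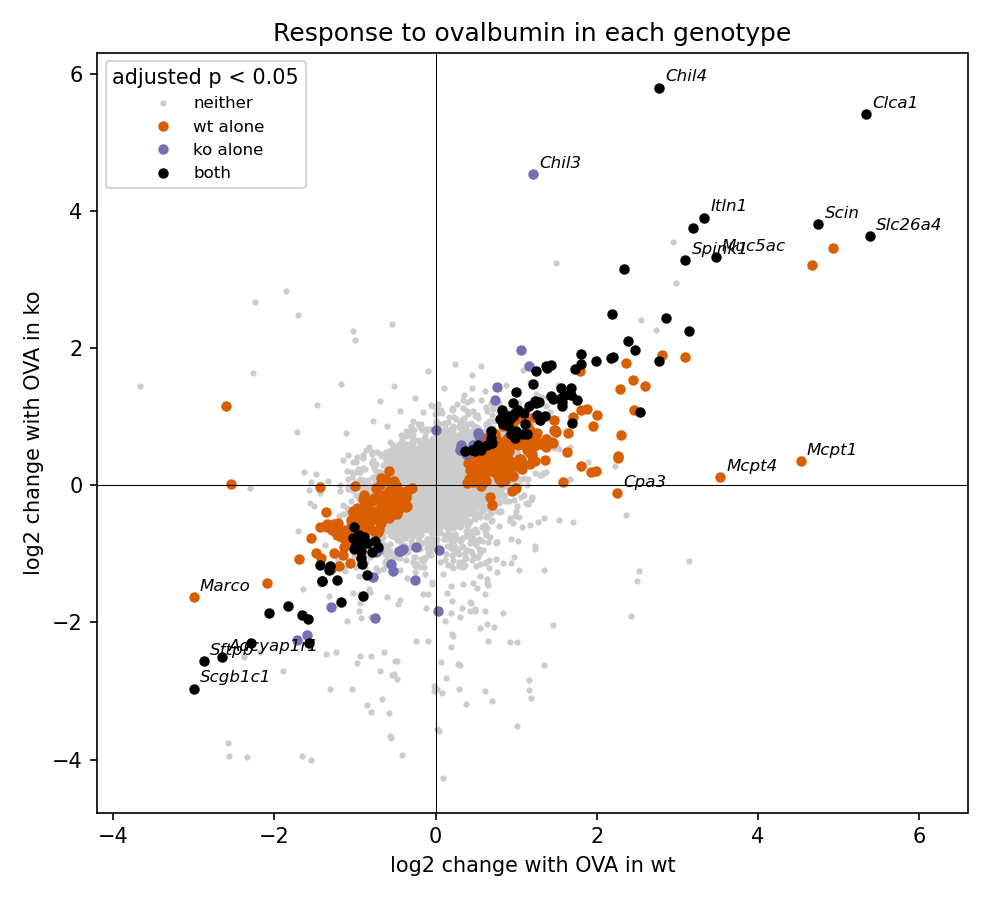
Log2 change with OVA in wt (x axis) against that in ko (y axis), 1 point per gene tested, coloured by the genotypes in which the adjusted p was below 0.05. Clca1 lay at 5.34 in wt and 5.41 in ko, whereas Mcpt1, at the floor on all saline arrays, lay at 4.53 in wt and 0.35 in ko.

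The comparison of ko with wt after saline asked what loss of the integrin alone changes. Transcripts of mast cells dominated it. Cpa3 was higher in ko by 5.19 ± 0.29 on the log2 scale (SE, n = 4 and 4, adjusted p = 4.23e-07), Mcpt4 by 5.08 ± 0.42 (adjusted p = 1.35e-05), Cma2 by 5.01 ± 0.29 (adjusted p = 4.65e-07), Cma1 by 4.75 ± 0.32 (adjusted p = 1.63e-06) and Tpsb2, a tryptase, by 4.72 ± 0.29 (adjusted p = 6.57e-07). Il1rl1, the receptor of IL-33, was higher by 4.14 ± 0.32 and Tph1, which makes serotonin, by 2.92. Gata2, a transcription factor, and Fcer1a, a chain of the IgE receptor, were at the floor on all wt_saline arrays and higher in ko by at least 2.94 and 2.68. Tpsg1, another tryptase, was not above background on any wt_saline array and was higher by at least 2.99 on the log2 scale. Mcpt1, in contrast, was at the floor on all 4 arrays of both groups, and Mcpt2 was at the floor on 3 of 4 arrays in each.

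Of 17 mast cell genes 11 were higher in ko after saline, 0 were lower and 6 did not pass, with a median of 2.68 (adjusted p = 0.00429 with an estimated correlation). The medians of other cell types were 0.54 for B and plasma cells, 0.38 for fibroblasts and smooth muscle, 0.32 for endothelium, 0.08 for macrophages and dendritic cells and 0.00 for T cells, and no gene of these lists passed over all genes. In the B and plasma cell list 3 genes were higher in ko when adjusted over the list alone, Ms4a1 (at least 2.83, at the floor on all wt_saline arrays) and Cd79b (1.63) among them. The striated muscle list had a median of 1.65 with no gene that passed (adjusted p = 0.747 with an estimated correlation), and medians of 1.98, -4.91 and 6.34 within slides. The eosinophil list had a median of -1.5 with 1 of 4 genes lower (adjusted p = 0.381 with an estimated correlation). Ear1 (-3.89 ± 0.54, adjusted p = 0.00358) and Ear10 (-3.39 ± 0.27, adjusted p = 8.93e-06), ribonucleases of eosinophils and macrophages, were lower in ko. Chil3 (-5.06 ± 0.89, adjusted p = 0.0349) and Chil4 (-4.02 ± 0.64, adjusted p = 0.0201) were lower too, but Chil4 lost its call without wt_saline 2, 3 or 4 or ko_saline 1, 2 or 4, and Chil3 without any of 11 single arrays, which included all 4 of wt_saline. With array position as a fixed block Ear1 (-3.69), Chil3 (-4.73) and Chil4 (-3.70) lost their calls at differences of similar size. Ear10 passed (adjusted p = 0.0133), and the counts were 14 higher and 1 lower. Limma called 23 genes higher and 7 lower, of which 22 and 6 differed at least 2-fold. All 15 named genes called kept their sign on each of the 3 slides that hold both groups, and the mast cell list had medians of 2.28 to 2.82 there. The count rose to 46 without ko_saline 4 and to 46 without ko_OVA 4.

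**Figure D2:**
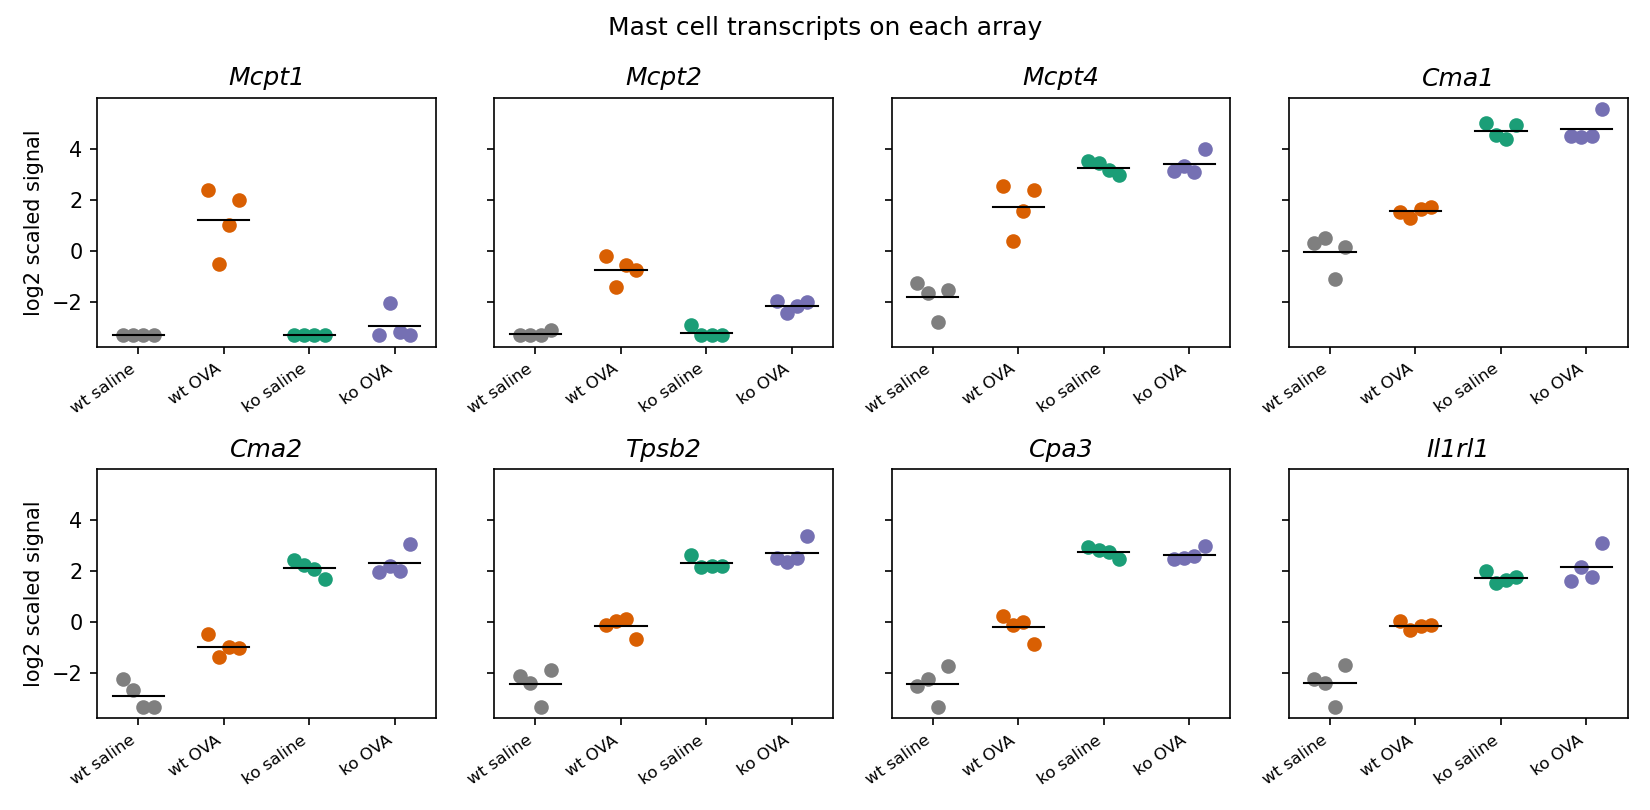
Log2 signal relative to the 75th percentile for 8 mast cell genes, 1 point per array and a line at the mean of each group of 4. Cpa3 had means of -2.45 in wt_saline, -0.20 in wt_OVA, 2.75 in ko_saline and 2.64 in ko_OVA, whereas Mcpt1 left the floor mainly in wt_OVA, with a mean of 1.21.

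After OVA the comparison of ko with wt asked how the inflamed epithelium differs without the integrin. The mast cell genes Cma2 (3.27 ± 0.29, adjusted p = 0.000192), Cma1 (3.22 ± 0.32, adjusted p = 0.000328), Tpsb2 (2.85 ± 0.29, adjusted p = 0.000328) and Cpa3 (2.84 ± 0.29, adjusted p = 0.000328) remained higher in ko (SE, n = 4 and 4). Fcer1a (2.57), Tpsg1 (2.36), Il1rl1 (2.30), Gata2 (adjusted p = 0.00311), Slc18a2, a transporter of amines (1.90), and Chst1, a sulfotransferase whose gene lies 32 Mb from Itgb6 (1.88), were higher too. The mucosal proteases went the other way: Mcpt1 was lower in ko by -4.18 ± 0.47 (adjusted p = 0.000668) and Mcpt2 by -1.42 ± 0.20 (adjusted p = 0.00537). Mcpt1 lost this call under 2 of 24 alternatives, normexp and only the arrays of the groups compared, and lay at the floor on 2 of the 4 ko_OVA arrays. Mcpt2 lost it under 6 of 24, with an adjusted p of up to 0.999, among them median scaling, the lower floor and the series matrix values. Mcpt1 reached -0.54 to 2.37 on the 4 wt_OVA arrays and -3.32 to -2.04 on the 4 ko_OVA arrays. Ear10 was lower by -2.52 ± 0.27 (adjusted p = 0.000431), and Ear1 by -3.31 ± 0.54 (adjusted p = 0.0202), a call lost without wt_OVA 1, 3 or 4 or ko_OVA 1, 2 or 3. The eosinophil list, which holds Ear1, had means of -3.32 to -3.20 on ko_OVA 1, 2 and 3. These lie at or near the floor, so the size of the Ear1 difference and its error depend on the floor. Mcpt4 did not pass (1.67 ± 0.42, adjusted p = 0.388). With normexp 11 of the 16 named calls were lost, among them Fcer1a (1.55, adjusted p = 0.0685), Tpsg1 (1.16, adjusted p = 0.922), Gata2 (1.16, adjusted p = 0.557), Slc18a2 (0.88, adjusted p = 0.999), Chst1 (1.03, adjusted p = 0.557) and Ear10 (-1.89, adjusted p = 0.136). With only the arrays of the groups compared 10 were lost, Tpsg1, Il1rl1, Gata2, Slc18a2 and Chst1 among them. Array position as a fixed block lost 5, with Il1rl1 and Gata2 among them, and slide as a fixed block lost Il1rl1 (adjusted p = 0.0512) and Ear1 (adjusted p = 0.0684). Cma2, Cma1, Tpsb2 and Cpa3 kept their calls under every alternative in which they were tested.

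Of 17 mast cell genes 9 were higher and 2 lower in ko after OVA, 12 and 2 when adjusted over the list alone, with a median of 1.90 (adjusted p = 0.0226 with an estimated correlation). The mucous cell list had a median of -0.12 and no gene that passed. Limma called 19 genes higher and 8 lower, of which 18 and 7 differed at least 2-fold, and leaving out single arrays gave 25 to 31. All 16 named genes called kept their sign on each of the 3 slides that hold both groups, where the mast cell list had medians of 1.74 to 2.50 and Mcpt1 differed by -5.31 to -2.67. The calls after saline and after OVA shared 17 higher genes and 4 lower genes, where 0.0235 and 0.00302 would be shared if the calls were independent. They are not fully so, since both comparisons use the same variance estimate for each gene.

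Whether the response to OVA itself differed between genotypes was asked with the interaction. Over all genes limma called 0, with 569 at an unadjusted p below 0.05 and a smallest adjusted p of 0.155. Among the genes named by the rule Mcpt1, Mcpt4 and Cpa3 had the smallest adjusted p. The differences were Mcpt4 -3.41 ± 0.60, Cpa3 -2.36 ± 0.41 and Tpsb2 -1.87 ± 0.41 (SE), with adjusted p of 0.24, 0.24 and 0.675 over all genes. Mcpt1 was at the floor on all 8 saline arrays, so its interaction of -4.18 (adjusted p = 0.19) is only the difference of ko from wt after OVA. Other named genes differed by as much or more with wider errors, S100a9 by 5.12 ± 1.76 and Il1b by 4.19 ± 1.15 (adjusted p = 0.993 for both). When adjusted over the list alone 8 of 17 mast cell genes had a lower log2 change with OVA in ko than in wt, and the list had a median of -0.94 (adjusted p = 0.0426 with an estimated correlation). Saline levels were unlike, with Cpa3 at a mean of -2.45 in wt_saline and 2.75 in ko_saline. From a higher level an equal gain in signal gives a smaller log2 change, so a smaller gain in ko is not shown. Other lists with large median interactions included striated muscle (-3.03), adipocytes (-1.55) and B and plasma cells (-0.76), none of which held with an estimated correlation (adjusted p = 0.599, 0.52 and 0.405 with an estimated correlation). The lists of endothelium (-0.60) and MHC class II (-0.46) had every gene below 0 and did not hold either (adjusted p = 0.405 and 0.385 with an estimated correlation). In the other direction the club cell list had a median of 0.49 with all 19 genes above 0, and the basal cell list 0.45 with 16 of 17 above 0 (adjusted p = 0.312 and 0.236 with an estimated correlation). The count over all genes was 3 without wt_OVA 2 and 1 without ko_saline 4, without ko_OVA 1 or without ko_OVA 4. The mucous cell list had a median interaction of -0.05 (adjusted p = 0.981 with an estimated correlation).

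**Figure D3:**
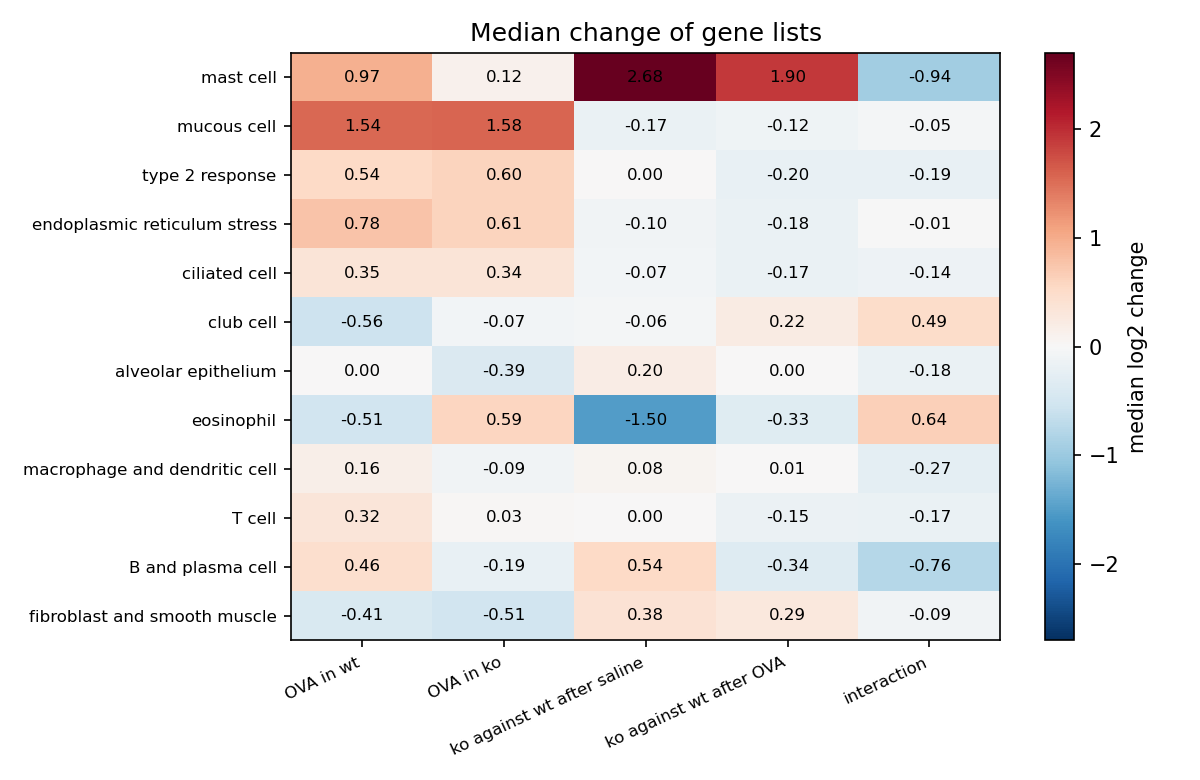
Median log2 change of 12 gene lists (y axis) in the 4 comparisons and the interaction (x axis), with colour for sign and size. The mast cell list was at 2.68 between ko and wt after saline, and the mucous cell list was at 1.54 and 1.58 with OVA in wt and in ko.

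DNA of another strain can remain around a knocked-out gene, so the genes within 20 Mb of Itgb6 on chromosome 2 were compared with the rest. After saline 1 of 110 was called, Rprm (1.30), against 23 of 12739 elsewhere (Fisher's exact p = 0.187). After OVA 2 of 110 were called, Abcb11 (-0.82) and Pla2r1 (1.07), against 20 elsewhere (Fisher's exact p = 0.015). Pla2r1 was not above background on any wt_OVA array, so its difference is a lower bound, and both calls were fragile. Abcb11 lost its call under 10 of 24 alternatives and Pla2r1 under 4, normexp (adjusted p = 0.999), only the arrays of the groups compared (adjusted p = 0.227), array position as a fixed block (adjusted p = 0.0614) and the higher floor (0.26, adjusted p = 0.917). After saline Abcb11 was at the floor on all 8 arrays, which leaves no difference to measure, and Pla2r1 did not pass (at least 0.27, adjusted p = 0.856). Rprm was named after its values were seen, and it did not pass after OVA (0.32, adjusted p = 0.884). Within 50 Mb 5 of 483 genes were called after OVA (Fisher's exact p = 0.00114) and 3 after saline (Fisher's exact p = 0.0595). Of these Chst1 (2.55 and 1.88) and Enkur (1.57 and 1.17), a gene at -39.4 Mb named after its values were seen, were called higher in ko after both saline and OVA.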

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

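The tests of cell types and muscle carried along, of slide, of array position and of Y-linked transcripts were chosen after the results were seen, whereas those of other splits of the arrays and of neighbours of Itgb6 were written before.

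The log2 change of 8 mast cell genes with OVA differed between genotypes when adjusted over the mast cell list alone. Adjusted p was 0.000293 for Mcpt1, 0.000293 for Mcpt4, 0.000293 for Cpa3, 0.000684 for Mcpt2, 0.00161 for Tpsb2, 0.00241 for Cma2, 0.00304 for Il1rl1 and 0.00923 for Cma1, and it was 0.0426 for the list as a whole with an estimated correlation. Mcpt1 was at the floor on all 8 saline arrays, so its interaction is only the difference after OVA. Mcpt2 was at the floor on 3 of 4 arrays in each saline group, so its interaction is mostly that difference. All 8 had a lower log2 change with OVA in ko than in wt, and none passed over all genes, where limma called 0 with 569 at an unadjusted p below 0.05. All but Mcpt1 and Mcpt2 were already higher in ko after saline, with Cpa3 at a mean of -2.45 in wt_saline and 2.75 in ko_saline. From a higher level an equal gain in signal gives a smaller log2 change, so a smaller gain in ko is not shown for them. Of 100 splits of the arrays 2 gave as many mast cell genes, the real split included, with 11 the highest of the other splits and 8 the real value. Other splits mix wt and ko arrays, so the large difference between genotypes widens their errors and leaves few calls. This share therefore does not decide whether chance gave the real value. For all genes the real split gave 0 and the highest other gave 1; every split gives at least 0 (100 of 100 here), so that count decides nothing.

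Other lists had single genes whose response differed when adjusted over their list alone. These were Il1b among alarmins and epithelial chemokines (0.0451), Fn1 among TGF-beta targets (0.046), and Cd302 (0.0203), Pla2r1 (0.0203) and Dpp4 (0.0271) among the neighbours of Itgb6. None of them passed over all genes.

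Mast cell transcripts were far higher in ko than in wt after saline, with a list median of 2.68. If connective tissue or other leukocytes were carried along, their own abundant transcripts were predicted to rise to a like degree. The highest median among 5 lists of such cells was 0.54, for B and plasma cells. Those cells as a whole did not rise to that degree. Single B cell genes differed more, Ms4a1 by at least 2.83 and Cd79b by 1.63, without passing over all genes. The prediction is too strict on the log2 scale for dim genes, since Cpa3, for one, had a mean of only -2.45 in wt_saline against a floor of -3.32. A little tissue with mast cells could raise such genes far more than transcripts already present, so carry-over stays open. This reasoning is weaker for brighter members. Cma1 had means of -0.04 in wt_saline and 4.72 in ko_saline, and Mcpt4 of -1.82 and 3.26. Striated muscle carried along was a separate case, since its list had a median of 1.65, but it went from -4.91 to 6.34 within slides. With the mean of the striated muscle genes as a covariate the median of the mast cell list was 2.65, which argues against it. With array position as a fixed block it was 2.51. Position 2 held only wt arrays and position 3 only ko arrays, so this block separates position from genotype poorly. Only position 1 held both saline groups. There Cpa3 was at -1.71 on wt_saline 4 and at 2.93 and 2.76 on ko_saline 1 and 3, a difference that position cannot give. With so few arrays there, a part played by position stays open. Within slides the lowest median of the mast cell list was 2.28, which argues against slide. With the level of 2 Y-linked transcripts as a covariate the median was 2.63, which argues against that level as the cause. A biological hypothesis is that loss of the integrin changes the number or the state of mast cells in the airway epithelium. No test here separates number from state, since that needs counts of cells. The litter of the mice is not in the labels and stays open.

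Ear1, Ear10, Chil3 and Chil4 were lower in ko than in wt after saline. Fewer macrophages and dendritic cells as a class would lower the whole of their list, whose median was 0.08. The members of that list went both ways, so a change in a subset of these cells stays open. On each slide that holds both groups all 4 genes were lower in ko, with -3.11 the smallest difference, which argues against slide. Array position stays open: with it as a fixed block the differences were -3.69 ± 0.84 for Ear1, -3.25 ± 0.42 for Ear10, -4.73 ± 1.16 for Chil3 and -3.70 ± 0.61 for Chil4 (SE), against -3.89 ± 0.54, -3.39 ± 0.27, -5.06 ± 0.89 and -4.02 ± 0.64 without it. Their adjusted p were 0.558, 0.0133, 0.81 and 0.112, so only Ear10 passed, in a model with fewer degrees of freedom and wider errors for all but Chil4. Eosinophils or alveolar macrophages may have been fewer in ko. The eosinophil list, which holds Ear1, had a median of -1.5 (adjusted p = 0.381 with an estimated correlation), and Marco (-2.05) and Itgax (-1.35) were lower on each of the 3 slides without passing over all genes, so this hypothesis stays open.

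Among genes near Itgb6, DNA of another strain around the knockout could add differences that owe nothing to the integrin. The saline and OVA differences of the 110 genes within 20 Mb had r = -0.068, and 24.7% of 97 runs of neighbouring genes elsewhere had a lower r. That value met the bound set beforehand against this explanation. After it was seen, the bound was judged wrong, because 110 mostly unchanged genes dilute the few that differ. The calls of Abcb11 and Pla2r1 after OVA (Fisher's exact p = 0.015) were the other reason. After saline Fisher's exact p was 0.187, and none of these p-values was adjusted for the windows and comparisons tried. After saline neither gene can tell: Pla2r1 did not pass (at least 0.27, adjusted p = 0.856), but its difference is only a lower bound, and Abcb11 was at the floor on all 8 saline arrays. The 2 calls were lost under 10 and 4 of 24 alternatives, Abcb11 and Pla2r1 in that order. Within 5 Mb 1 gene was called after OVA (Fisher's exact p = 0.0354), and within 50 Mb 5 were (Fisher's exact p = 0.00114), with Chst1 and Enkur higher in ko after both agents. The effect of such DNA and that of the knockout cannot be told apart for these genes.

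Other splits of the 8 arrays of each comparison were counted, 35 in each case. For OVA in wt 1 split, the real one, gave as many as 485 genes, and the highest other gave 5. For OVA in ko 1 split gave as many as 139, and the highest other gave 2. For ko against wt after saline 1 split gave as many as 30, and the highest other gave 1. For ko against wt after OVA 1 split gave as many as 27, and the highest other gave 5. The real split stood alone in each case, which is the strongest result that 35 splits can give. It argues against chance for each count but cannot exclude it.

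Single arrays lay far from the others of their group in 19 of 346 groups of 4 tested, where chance marks about 1 in 20 groups, so the number is near what chance gives. Each value here is the gap to the nearest array divided by the range of the group. In ko_OVA array 4 stood apart and higher for Cma1 (0.949; 5.55 against 4.46 to 4.52) and Tpsb2 (0.843), lower for Scnn1b (0.879), apart for Slc18a2 (0.864), and higher for the eosinophil list (0.955). Other arrays of ko_OVA stood apart for Pdia4 (0.934), Dclk1 (0.87) and the alveolar epithelium list (0.832). In ko_saline array 4 stood apart for Rab6b (0.91), C6 (0.864), Kdr (0.859) and Rptn (0.855), and lay lower for Gata2 (0.9), whereas other arrays did so for Tpsb2 (0.853) and the squamous and oesophageal epithelium list (0.933). In wt_OVA array 2 lay lower for Scin (0.915) and array 4 stood apart for Cd302 (0.847). In wt_saline array 1 was higher for Krtap17-1 (0.871) and array 2 stood apart for Manf (0.905).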

How the results depend on the processing

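Alternatives with a floor of another height, with a further filter, with a covariate, and without the pair of arrays named below were chosen after seeing the data. No named gene that was called and none of the 12 list results tested again reversed its sign over all slides (single slides can differ), but the balance of calls with OVA in wt turned over under median scaling. The cause was not tested except where given.

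With OVA in wt, 485 genes became 130 with normexp, 100 with median scaling, 1364 with array weights, 235 with only the arrays of the groups compared (fewer samples in the fit) and 94 with array position as a fixed block. With OVA in ko, 139 became 63 with normexp, 35 with median scaling, 329 with array weights and 7 with only the arrays of the groups compared. In ko it was 91 with Y-linked transcripts as a covariate and 62 with striated muscle genes as a covariate. Median scaling split the calls into 39 higher and 61 lower in wt and 23 and 12 in ko, with the median of all genes at -0.246 in wt.

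Between ko and wt after saline, 30 became 55 with no background correction and quantile normalization, 55 with the series matrix values, 19 with probes well above background on all 16 arrays (fewer genes tested), 109 with array weights and 15 with array position. It was 61 without ko_OVA 4 and wt_OVA 1, the dimmest array and the one with the most probes above background. After OVA, 27 became 7 with normexp, 7 with only the arrays of the groups compared and 11 with probes above background on all 16 arrays. The median of all genes moved to 0.323 there under median scaling.

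The interaction count of 0 became 1 with array weights, 1 with slide as a fixed block and 1 without that pair of arrays.

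Slide as a fixed block gave 344, 99, 29 and 24 genes. The replicate block gave 370, 103, 27, 24 and 0, but replicate numbers did not pair the arrays: 5 of 24 same-numbered pairs were best matches.

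Leaving out single arrays gave 236 to 540 genes for OVA in wt, lowest without wt_saline 1 or 2 (236 each) and 270 without wt_OVA 3. For OVA in ko it gave 67 to 168, with 67, 71 and 88 without ko_saline 1, 2 and 3, and 75 and 83 without ko_OVA 2 and 4. For ko against wt after saline it gave 24 to 46, with 46 without ko_saline 4 or ko_OVA 4. After OVA it gave 25 to 31. The interaction gave 0 to 3, with 3 without wt_OVA 2 and 1 without ko_saline 4, ko_OVA 1 or ko_OVA 4. The correlation of the OVA responses ran from 0.339 to 0.565, and from 0.399 to 0.584 over the other alternatives. The dimmest array, ko_OVA 4, had 43.3% of probes above background, which limits what dim genes can show.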

Other observations

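Some transcripts of other tissues varied between arrays within groups. Myh4, a myosin of skeletal muscle, reached log2 5.82 on wt_OVA 1, 6.74 on ko_saline 2 and 5.24 on ko_saline 3, against a floor of -3.32. Tg, the thyroid protein thyroglobulin, ran from -1.27 to 7.30 over the 16 arrays. Ms4a1, a B cell gene, was at 1.32 on wt_OVA 1 and at 0.18, 0.40 and 0.81 on ko_saline 1, 2 and 3, and at the floor on the other arrays. The striated muscle list had a median of -3.31 with OVA in ko, and none of its 12 genes passed over all genes.

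On ko_OVA 4, the dimmest array, Il4 was at 1.05, Ccr3 at -0.45, Ear6 at 0.30 and Srgn at 5.10. The other 3 arrays of that group had Il4 at or below -2.20 and Ccr3 at or below -2.99. On wt_saline 4 Clca1 was at 6.19, against 2.31 to 3.17 on the other wt_saline arrays.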
